A study of Mus musculus with 9 samples.

How the data were processed

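The deposited values form 1 column per library for 9 libraries, with whole numbers for 43629 Ensembl gene identifiers of the GRCm38 genome. Its values have the unit score: the authors divided read numbers per gene by 1 size factor per library and rounded them before the table was deposited, which was read from the values. Per the submitters' processing notes, CASAVA 1.8.2, STAR 2.4, RSEM and DESeq2 were used, without their order or roles, and the annotation release is not stated. Rounding leaves gaps or doublings at regular places among the low values of a library, such as no gene at 3 or 10 in WT library 3, and a search over these gaps gave the size factors. This search was tested on simulated data with 48 factors, where 1 was wrong by over 1% (by 3.67%, for a true factor just below 1) and was fitted as a factor of about 1. The depths derived from it are estimates, used only here and to set replicate differences beside sampling noise. Symbols and positions came from GENCODE M21: 42462 identifiers had a symbol, 1167 had none, and 40 shared a symbol with another. The values of 17778 identifiers were 0 in all libraries and those of 25851 were above 0 in at least 1.

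The design fixed before the values were seen assumed raw counts and named a count test. The values are normalised, so no count test was run and the alternative stated in that design was used: limma 3.58.1 with a mean-variance trend on log2(value + 1), over 9 libraries in 3 groups, without a replicate block. Genes with a value of at least 10 in at least 3 libraries were tested, and p-values are 2-sided and adjusted by Benjamini-Hochberg at 0.05. A fold change is therefore on the log2(value + 1) scale, which understates changes of low genes. All 29 gene lists were written before the values were seen and tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. The level of a list in a library is the mean over its members of log2(value + 1) minus the mean of each gene over all libraries. Genes named as largest changes are the 10 with the largest log2 fold changes per direction in each of the first 2 comparisons, by a rule fixed in the design. They had to pass the test, average at least 5 CPM over the 9 libraries, show no overlap between the groups and carry a symbol other than a Gm, Rik or pseudogene name. Others are the targets and, for each list, up to 4 members with the smallest adjusted p.

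Alternatives run were other filters, relative log expression and upper-quartile factors, limma-voom with and without sample weights, fits of only the 2 groups compared, a block for the replicate number, a test against a 1.5-fold change, sex-linked genes left out and each library left out in turn. Other pseudocounts, scaling to the column total with or without the late neutrophil genes, quantile normalisation and limma without the trend were chosen after seeing the data. The planned fits with edgeR and DESeq2 need raw counts and were not run, and a sex covariate was not fitted because Xist was high in each library and no Y-linked gene of the sex-linked list reached the filter, although the level of Xist differed between groups. The test for opposite directions drew 100 simulations with no change in KI_Chd7del. The recovery of set changes was tested on simulated data in 20 runs. Software was R 4.3.3 with the package data.table at version 1.17.8, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.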

Results

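Bone marrow cells carrying c-KIT, the stem cell factor receptor of haematopoietic stem and progenitor cells, were profiled by RNA-seq in 3 groups of mice, with 3 libraries per group. All mice had received pIpC, a synthetic double-stranded RNA that raises interferon and thereby switches on Cre recombinase from the Mx1 promoter. The first group was labelled wild type (WT). The second carried Mx1-Cre and the Cbfb+/56M allele, a conditional knock-in of the CBFB-MYH11 fusion found in human acute myeloid leukaemia (KI). The third carried the same alleles and was floxed for Chd7, a chromatin remodelling ATPase, on both chromosomes (KI_Chd7del). The labels do not state that the libraries of a group came from separate mice, so p-values measure the spread between these samples.

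The deposited table held 43629 Ensembl genes with 1 value per library, read numbers scaled by a size factor and rounded to whole numbers, called normalised values here. Their totals ran from 43.2 to 46.2 M in WT, from 37.7 to 39.0 M in KI and from 37.5 to 38.1 M in KI_Chd7del. The pattern of low values placed the size factors between 0.852 and 1.19, which corresponds to 39.3 to 47.5 M reads per library. A normalised value of 1 thus stood for about 1 read, and the precision of low values was limited by counting. Between 20329 and 21964 genes were above 0 in a library, and 15997 genes reached 10 in at least 3 libraries and were tested. Within groups, the median squared difference between 2 replicates was 3.35 to 14.0 times that of sampling noise. The 10 most abundant genes took 12.6% to 14.4% of the total in WT, 4.66% to 5.08% in KI and 6.64% to 7.89% in KI_Chd7del. Mitochondrial transcripts took 1.53% to 1.62%, 1.83% to 2.06% and 2.18% to 2.97%, with the highest share in KI_Chd7del library 1.

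The 3 groups separated by their whole expression profiles. The first principal component, with 63.4% of the variance, placed WT libraries between -89.7 and -82.4 and KI libraries between 64 and 90.2. The KI_Chd7del libraries lay between them, from -1.1 to 16.9. The second component, with 18.4%, set the KI_Chd7del libraries (-52.3 to -49.2) apart from both WT (14.9 to 24.7) and KI (27.7 to 34.3). KI_Chd7del library 1 stood apart from its group on the third component (5.3% of the variance), at 45.9 against -19.5 and -28.7.

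**Figure D1:**
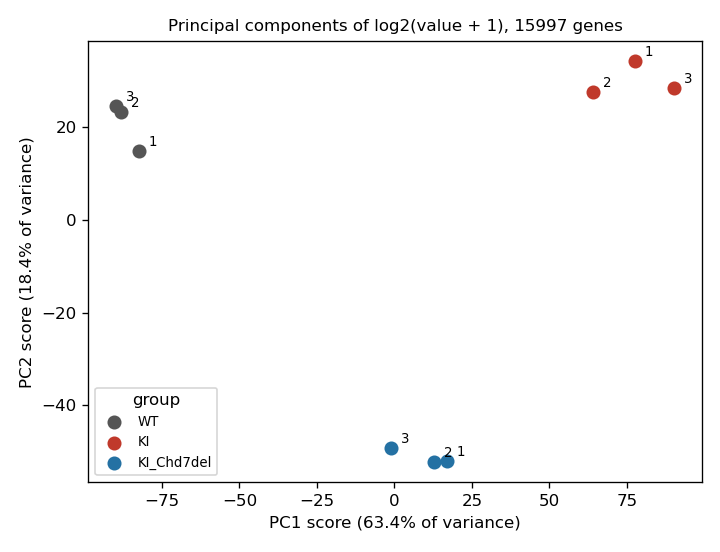
Scores of the 9 libraries on the first 2 principal components of log2(value + 1) over 15997 genes, in arbitrary units, with 1 point per library and colours for the groups. KI_Chd7del lies between WT and KI on the first axis (63.4% of the variance) and below both on the second (18.4%).

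The genes altered by the alleles were examined first. Chd7 (ENSMUSG00000041235, chromosome 4, 8690406 to 8867659, GRCm38) had normalised values of 3471, 3745 and 3982 in WT, 1979, 2934 and 2009 in KI, and 1862, 1794 and 1921 in KI_Chd7del. Chd7 fell in KI against WT (log2 fold change -0.72, SE 0.14, adjusted p = 0.00154) and in KI_Chd7del against WT (to 0.499 of WT, SE 0.14 on the log2 scale, adjusted p = 0.000374). Each KI_Chd7del library lay below each KI library for Chd7, yet that difference of -0.29 did not pass the test (SE 0.14, adjusted p = 0.121). A value summed over the whole gene cannot show the loss of an internal exon, so Chd7 gives a weak check of the floxed genotype here. Cbfb (ENSMUSG00000031885, chromosome 8, 105170674 to 105217989), which encodes core binding factor beta, did not pass the test in any comparison (log2 -0.06, -0.01 and -0.07, each with SE 0.06). The direction of Cbfb against WT depended on the scaling. With upper-quartile factors it was lower in KI (-0.16, adjusted p = 0.0462), and scaled to the column total it turned to 0.17 in KI, which did not pass, and to 0.18 in KI_Chd7del (adjusted p = 0.0488). Myh11 (ENSMUSG00000018830, chromosome 16, 14194535 to 14291372), the smooth muscle myosin heavy chain gene that gives the fusion its tail, was at 8, 9 and 5 in WT. It reached 219, 194 and 176 in KI, a 24.1-fold rise (log2 4.59, SE 0.22, adjusted p = 5.14e-07), and 187, 164 and 176 in KI_Chd7del. Myh11 in KI_Chd7del differed from KI by -0.16 (SE 0.22, adjusted p = 0.591). Kit (ENSMUSG00000005672, chromosome 5, 75574916 to 75656722), the gene of the receptor used for selection, fell in KI from 7504 ± 253 to 3538 ± 321 (SD, n = 3; log2 -1.09, SE 0.11, adjusted p = 3.88e-05). Kit stood at 7457 ± 1212 in KI_Chd7del, a rise against KI of 1.07 (SE 0.11, adjusted p = 0.000212). Xist, the RNA that silences an X chromosome and a check of sex, had 8052, 9364 and 9049 in WT, 18868, 35731 and 26325 in KI, and 17810, 17987 and 16437 in KI_Chd7del. It was thus high in each library but differed between groups, by 1.57 in KI against WT (SE 0.19, adjusted p = 9.33e-05) and by 0.98 in KI_Chd7del against WT (adjusted p = 0.00244). Against KI it differed by -0.58 (adjusted p = 0.0351), a call lost when leaving out KI library 2 or 3, KI_Chd7del library 1, 2 or 3, or WT library 2 or 3 (0.0504 to 0.092) and with several other settings (0.0532 to 0.0715).

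**Figure D2:**
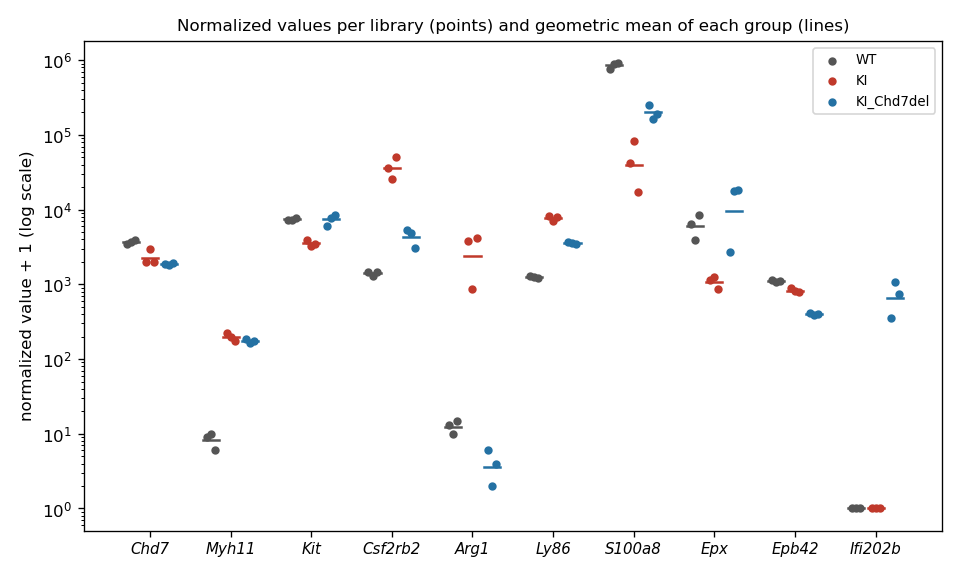
Normalised value + 1 of 10 genes in each of the 9 libraries, on a log axis, with 1 point per library, colours for the groups and a line at the geometric mean of each group. Myh11 lies between 164 and 219 in all 6 libraries with the fusion allele and between 5 and 9 in WT, and Ifi202b is at 0 outside KI_Chd7del.

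The first comparison set c-KIT+ marrow with the fusion allele and Chd7 intact against WT. KI also carried Mx1-Cre, which the WT label does not name, so effects of the fusion and of Cre are measured together. Transcripts of maturing neutrophils fell in KI, while those of monocytes, of antigen presentation and of some mast cell genes rose. The list calls for the neutrophil, monocyte and antigen presentation genes were lost with an estimated correlation (adjusted p = 0.531 to 0.701). The list of mast cell, basophil and eosinophil genes had no call to lose, with 10 of 20 higher and 8 lower (camera adjusted p = 0.75). S100a8, a calcium-binding protein abundant in neutrophils, averaged 852890 ± 73507 in WT and 47215 ± 32958 in KI (SD, n = 3; log2 -4.44, SE 0.46, adjusted p = 3.78e-05). Ccr2, the chemokine receptor of inflammatory monocytes, rose from 2457 ± 375 to 35854 ± 2627 (log2 3.88, SE 0.15, adjusted p = 2.42e-07). Ms4a2, the beta chain of the high-affinity IgE receptor, rose from 938 ± 86.5 to 27614 ± 4913 (log2 4.87, SE 0.18, adjusted p = 1.96e-07). Of 15997 genes, 9429 (58.9%) passed an adjusted p of 0.05 with limma, 5084 higher and 4345 lower in KI. At least 2-fold changes were seen in 2314 and 1347 of them. In 10819 genes (67.6%) the libraries of the groups did not overlap, against 10% by chance. The higher genes made up 53.9% of the calls, and 74.2% when values were scaled to the column total, which moved the median of all genes from 0.02 to 0.25. With upper-quartile factors and quantile normalisation they were the minority, at 45% and 44.9%.

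The 10 largest rises in KI were led by Mcpt1, a mast cell protease, with 20, 1 and 0 in WT and 16539, 18321 and 21135 in KI (adjusted p = 2.96e-05). Tph1, the tryptophan hydroxylase of serotonin synthesis outside the brain, had 11, 0 and 0 in WT and 10591, 3788 and 11921 in KI. Wnt2, a Wnt ligand, had 2, 0 and 0 against 2399, 1782 and 3235. Gsg1l followed with 5, 0 and 0 against 2729, 2134 and 3158. Retnla, a resistin-like protein of alternatively activated macrophages, had 48, 2 and 12 against 17928, 6702 and 21170. The list went on with Ccl24, an eosinophil chemokine, C2cd4a, Maob, a monoamine oxidase, and Mcpt2, another mast cell protease. These had log2 fold changes of 9.46, 9.33, 9.17 and 9.01 and adjusted p of 5.95e-07 to 3.65e-05. Dnase2b, an acid DNase, was listed at 0 in the WT libraries and had 543, 335 and 591 in KI. The largest falls were those of Ear6, an eosinophil-associated ribonuclease, from 1273, 821 and 2336 to 1, 0 and 0 (adjusted p = 2.05e-05), and of Sh3tc2, from 942 ± 60.7 to 1.33 ± 0.577. Aldh1a7 (log2 -6.98) and Aldh1a1 (-6.19), the latter a retinaldehyde dehydrogenase, came next with Cldn1, a tight junction claudin (-6.90). Sh2d4a (-6.03), Rasl11b (-4.96), Fbxo10 (-4.94), Slc6a12 (-4.81) and Chit1, a chitinase (-4.69), followed. Adjusted p of these last 8 ran up to 0.000601, that of Chit1. Values of Mcpt1, Mcpt2, Ear6 and Aldh1a7 carry extra uncertainty, since the authors' counting could divide reads between near-identical family members. For genes near 0 in WT or KI, the size and rank of the change depend on the pseudocount. With a pseudocount of 16, Ear6 moved from -10.06 to -6.38, Sh3tc2 from -8.68 to -5.79 and Dnase2b from 8.90 to 4.94, and each still passed.

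Granulocyte genes fell across both of their lists. All 20 late neutrophil genes fell in KI, and all 20 when adjusted over the list alone (median log2 -3.17, camera adjusted p = 1.18e-07; adjusted p = 0.701 with an estimated correlation). Among them were Ly6g, a neutrophil surface protein (-4.64), the antimicrobial peptide gene Camp (-4.12) and Fcnb, a ficolin (-3.62). The late list took 11.2% to 13.3% of the library in WT and 0.822% to 2.53% in KI. Of 12 early granule genes, 10 fell and none rose, or 11 when adjusted over the list alone (median -1.62, camera adjusted p = 3.77e-05; adjusted p = 0.613 with an estimated correlation). Among them were Cebpe, a transcription factor of granulocyte maturation (-3.41), Elane, neutrophil elastase (-2.31), and Prtn3, another granule protease (-1.25).

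Monocyte and macrophage genes went the other way, with 16 of 20 higher and 2 lower, or 17 and 2 when adjusted over the list alone (median log2 2.17, camera adjusted p = 1.24e-05; adjusted p = 0.531 with an estimated correlation). Ms4a6c rose by 2.64, Ly86, a partner of a Toll-like receptor homologue, by 2.62, and Mpeg1, a macrophage pore-forming protein, by 2.21. In the list of dendritic cell and class II genes, 13 of 16 were higher and 1 lower, or 14 and 1 when adjusted over the list alone (median 1.91, camera adjusted p = 0.000642; adjusted p = 0.531 with an estimated correlation). Its members Ciita, the class II transactivator, H2-DMb1 and H2-DMa, which load peptides, and Flt3, a progenitor receptor, rose by 3.93, 2.38, 2.13 and 1.59. Of 22 stem cell genes 11 were higher and 3 lower, the same counts when adjusted over the list alone (median 0.68, camera adjusted p = 0.0451; adjusted p = 0.701 with an estimated correlation). Tek, an angiopoietin receptor, rose by 4.55, Gata2, a stem and mast cell transcription factor, by 3.91, Ctnnal1 by 3.06 and Hlf, a stem cell transcription factor, by 2.13. This stem cell call was lost without KI library 1 or 3 (adjusted p = 0.0638 and 0.0521) and without WT library 2 or 3 (0.0614 and 0.0638). It was also lost with values scaled to the column total with or without the late neutrophil genes (0.213 and 0.0745), with quantile normalisation (0.0682) and with a pseudocount of 16 (0.0533).

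Proliferation genes were lower in KI. Of 26 DNA replication genes 22 fell and 2 rose, also when adjusted over the list alone (median log2 -0.48, camera adjusted p = 2.57e-07; adjusted p = 0.613 with an estimated correlation). Ccne1, cyclin E1, fell by 1.37, Rrm2, a ribonucleotide reductase subunit, by 0.92, Cdc45 by 0.82 and Cdc6, a licensing factor, by 0.76. Of 22 mitosis genes 16 fell and none rose, also when adjusted over the list alone (median -0.27, camera adjusted p = 9.98e-05; adjusted p = 0.701 with an estimated correlation). Cdk1, the mitotic kinase, fell by 0.70 and Birc5, survivin, by 0.67. With values scaled to the column total the medians of these lists moved to -0.25 and -0.04, and the change of Birc5 to -0.44. Of 24 oxidative phosphorylation genes 12 fell and 1 rose, also when adjusted over the list alone, with a median of -0.16 that turned to 0.07 when scaled to the column total. That call (camera adjusted p = 0.00661; adjusted p = 0.701 with an estimated correlation) was lost with this scaling (0.323) and with quantile normalisation (0.157). Among its lower genes were Ndufb7 (-0.77), Cox5a (-0.71), Ndufb3 (-0.69) and Ndufa4 (-0.43), subunits of respiratory complexes, and Ndufa4 moved to -0.20 when scaled to the column total.

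Chromatin remodeller genes were mostly higher, 15 of 24 with 3 lower, also when adjusted over the list alone (median log2 0.38, camera adjusted p = 0.00661; adjusted p = 0.613 with an estimated correlation). Scaled to the column total the median was 0.61. The higher genes included the Chd7 relatives Chd3 (2.04), Chd9 (1.05), Chd6 (0.90) and Chd8 (0.56). Chd7 itself is a member of this list and had its largest fall (-0.72). Of 22 genes linked to CBFB-MYH11 in earlier work, 13 were higher and 4 lower, also when adjusted over the list alone (median 0.74, camera adjusted p = 0.0451; adjusted p = 0.531 with an estimated correlation). Besides Myh11 (4.59) and Gata2 (3.91), its leading genes were Il1rl1, an interleukin receptor of mast cells (4.98), and Csf2rb2, a receptor subunit of the IL-3 type (4.67). That call was lost without KI library 1, 2 or 3 (adjusted p = 0.0638, 0.0931 and 0.0724) and without WT library 2 or 3 (0.0543 and 0.0501). Scaling to the column total, with or without the late neutrophil genes, also ended it (0.144 and 0.0685), as did the filter set per library total (0.108). The list holds Myh11, whose reads may come from the fusion itself, and was not tested without it.

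The other lists did not pass camera. The p53 target list had 9 of 19 genes higher and 2 lower, also when adjusted over the list alone (median log2 0.32, camera adjusted p = 0.122). Its leading genes were Phlda3 (4.08), Bbc3 (2.47) and Cdkn1a (2.28), regulators of survival, apoptosis and the cell cycle, and Bax (0.64). Without KI library 2 that list passed (median 0.40, adjusted p = 0.0442), as it did without a filter (0.0449). The 20 mast cell, basophil and eosinophil genes split into 10 higher and 8 lower (median 0.54, camera adjusted p = 0.75). Il1rl1 and Ms4a2 rose by 4.98 and 4.87, whereas Prss34, a basophil protease, and Prg2, the eosinophil major basic protein, fell by 2.83 and 3.14. Erythroid genes split into 9 higher and 10 lower, with a median of 0.13, a mean of 0.23 and a test direction that was down (camera adjusted p = 0.833). Aqp1, a water channel, fell (-3.31). Interferon response genes had 7 of 28 higher and 2 lower, or 5 and 0 when adjusted over the list alone (median 0.42, camera adjusted p = 0.446), with Mx1, the gene whose promoter drives Cre here, at 3.64 and the guanylate-binding protein gene Gbp2 at 3.23. In all, 10 of 29 lists passed camera and 0 did with an estimated correlation, whereas fry, which asks only whether a list moves one way on balance, called 16.

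**Figure D3:**
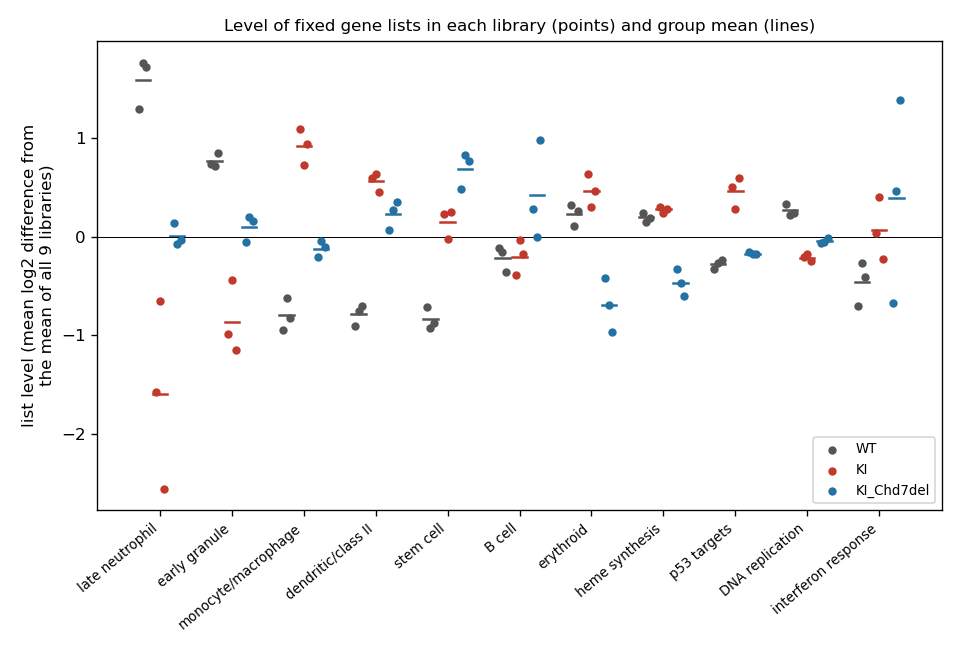
Level of 11 gene lists in each of the 9 libraries, as the mean over members of log2(value + 1) minus the mean of each gene over all libraries, with 1 point per library and colours for the groups. The late neutrophil level lies between 1.29 and 1.76 in WT, between -2.55 and -0.65 in KI and between -0.08 and 0.14 in KI_Chd7del.

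The second comparison asked what the Chd7 alleles changed on the fusion background, the question named in the series title. Any difference of strain background between these groups would be measured together with the Chd7 alleles. Granulocyte and B cell genes were higher in KI_Chd7del than in KI, and monocyte, erythroid and heme synthesis genes were lower. All these list calls were lost with an estimated correlation (adjusted p = 0.63 to 0.676). Fry called these lists too, except that of B cell genes (fry adjusted p = 0.0671). Arg1, arginase 1 of alternatively activated macrophages, had 3811, 855 and 4166 in KI and 5, 1 and 3 in KI_Chd7del (log2 -9.36, SE 0.61, adjusted p = 2.42e-05). S100a8 rose from 47215 ± 32958 to 203720 ± 46596 (SD, n = 3; log2 2.36, SE 0.46, adjusted p = 0.0041). Mrc1, the macrophage mannose receptor, fell from 8924 ± 2833 to 1315 ± 42.7 (log2 -2.71, SE 0.22, adjusted p = 6.67e-05). Epb42, a red cell membrane protein, fell from 826 ± 53.2 to 401 ± 10.1 (log2 -1.04, SE 0.07, adjusted p = 2.42e-05). Of 15997 genes, 6464 (40.4%) passed an adjusted p of 0.05 with limma, 2803 higher and 3661 lower in KI_Chd7del. At least 2-fold changes were seen in 723 and 1229 of them. The libraries of the groups did not overlap in 8315 genes (52%), against 10% by chance. Higher genes made up 43.4% of the calls. That share was 57% with quantile normalisation, 56.3% with upper-quartile factors and 53.6% when scaled to the column total without the late neutrophil genes. Among the 865 genes that passed a test against a 1.5-fold change it was 18.3%.

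Among the 10 largest rises, Ifi202b (ENSMUSG00000026535, chromosome 1, 173962568 to 173982744), a DNA-sensing protein of the interferon-inducible p200 family, was listed at 0 in the 6 WT and KI libraries. It had 355, 1074 and 751 in KI_Chd7del (adjusted p = 5.5e-06). Several of the others were eosinophil genes. The list of mast cell, basophil and eosinophil genes did not pass, with 8 of 20 higher and 8 lower (camera adjusted p = 0.654). Prg2 rose from 2327 ± 535 to 21317 ± 10918 (log2 3.04, SE 0.44, adjusted p = 0.000962) and Epx, eosinophil peroxidase, from 1090 ± 202 to 12773 ± 8712 (log2 3.14, SE 0.65, adjusted p = 0.00529). Prg3, Ear1 and Ear6, of the same cells, rose by 3.17, 3.56 and 3.56, and Alox15, a lipoxygenase, by 3.78. KI_Chd7del library 1 held less of these transcripts, with Epx at 2717 against 17553 and 18049 and Prg2 at 8735 against 28295 and 26920. Plagl1, an imprinted zinc finger gene, rose from 107 ± 35.4 to 962 ± 253 (log2 3.17, SE 0.28, adjusted p = 9.61e-05). Sh3tc2 rose by 3.78 (adjusted p = 0.00227). Hmga1b, a close copy of Hmga1, had 117, 2453 and 1269 in KI_Chd7del (log2 3.36, adjusted p = 0.0162). The call of Hmga1b was lost without KI_Chd7del library 3 (adjusted p = 0.0542) and with limma-voom (0.127), which also ended those of Ear1 (0.0566) and Ear6 (0.19). Ear6 and Sh3tc2 were at 0 to 2 in KI, so the size of their rises depends on the pseudocount. With a pseudocount of 5 that of Ear6 was 2.03, and with 16 it was 1.14 and the call was lost (adjusted p = 0.107), while that of Sh3tc2 was 1.54. Ear1, Ear6 and Hmga1b have near-identical relatives between which reads could be divided.

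Tph1, Retnla and Ccl24, of the 10 largest rises in KI, were also among the 10 largest falls here. Tph1 fell from 8767 ± 4363 to 97.7 ± 75.1 (log2 -6.97, SE 1.18, adjusted p = 0.00205). Ccl8, a monocyte chemokine, fell from 4931, 982 and 4147 to 66, 52 and 34 (log2 -5.77, SE 0.58, adjusted p = 0.00016). Vcan, the matrix proteoglycan versican, fell from 3110 ± 181 to 101 ± 28.5 (log2 -4.97, SE 0.23, adjusted p = 9.69e-06). Rnase2a, Wtip, Lypd6b and Ccl24 fell by 5.62, 5.30, 4.77 and 4.77 on the log2 scale (adjusted p 3.3e-05 to 0.00473). Retnla had 17928, 6702 and 21170 in KI and 3552, 127 and 8 in KI_Chd7del (log2 -6.42, SE 1.86, adjusted p = 0.0233). Its call was lost without KI library 1 or 3 (adjusted p = 0.0656 and 0.0661) and without KI_Chd7del library 2 or 3 (0.0626 and 0.0538). Ighv1-50, an immunoglobulin variable gene, fell by 4.93 (adjusted p = 0.0236), with 46, 116 and 3010 in WT. Its call was lost without KI library 1 (0.0794), KI library 3 (0.0512) or KI_Chd7del library 1 (0.0705), with limma-voom (0.295) and with a pseudocount of 16 (0.0982).

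The granulocyte lists rose. Of 20 late neutrophil genes 19 rose and none fell, also when adjusted over the list alone (median log2 1.74, camera adjusted p = 3.86e-06; adjusted p = 0.676 with an estimated correlation). S100a9, the partner of S100a8, rose by 2.17, Camp by 2.13 and Fcnb by 1.69. The late list took 4.02% to 5.21% of the library in KI_Chd7del. Of 12 early granule genes 11 rose, or 12 when adjusted over the list alone, and none fell (median 0.92, camera adjusted p = 1.23e-05; adjusted p = 0.63 with an estimated correlation). Gfi1, a repressor needed for neutrophil formation, and Nkg7 each rose by 1.25, Igsf6 by 0.87 and Prtn3 by 0.71. Monocyte and macrophage genes fell in 15 of 20 and rose in 3, or 15 and 4 when adjusted over the list alone (median -1.2, camera adjusted p = 3.76e-05; adjusted p = 0.63 with an estimated correlation). Besides Mrc1, the leading members were Ccr2 (-2.44), Mpeg1 (-1.38) and Ly86 (-1.12). Dendritic and class II genes did not pass as a list, with 3 of 16 higher and 7 lower, or 3 and 8 when adjusted over the list alone (median -0.57, camera adjusted p = 0.203). Its members Ciita (-2.20), Cd74, the invariant chain (-1.46), H2-DMb1 (-1.27) and H2-DMa (-0.80) fell.

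Erythroid genes fell in 20 of 24 and rose in 2, or 20 and 3 when adjusted over the list alone (median log2 -0.85, camera adjusted p = 1.04e-06; adjusted p = 0.63 with an estimated correlation). After Epb42 came Ank1, ankyrin 1 (-0.87), Ermap (-0.85) and Rhd, a blood group protein (-0.77). Of 13 heme synthesis genes 8 fell and 1 rose, also when adjusted over the list alone (median -0.73, camera adjusted p = 0.00239; adjusted p = 0.63 with an estimated correlation). Among them were Fech, ferrochelatase (-1.49), Abcb10 (-0.88) and Cpox (-0.77). Of 21 B cell genes 12 rose and 1 fell, or 13 and 1 when adjusted over the list alone (median 0.78, camera adjusted p = 0.0019; adjusted p = 0.676 with an estimated correlation). The leading members were Blk, a B cell kinase (1.82), and Vpreb2 (1.33), Igll1 (1.22) and Vpreb3 (1.12) of the pre-B cell receptor. Without KI_Chd7del library 3 the B cell median was 0.50 (adjusted p = 0.0145).

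Of 19 p53 target genes 10 fell and 2 rose, or 11 and 2 when adjusted over the list alone (median log2 -0.44, camera adjusted p = 0.0023; adjusted p = 0.63 with an estimated correlation). Phlda3 fell by 2.10, Cdkn1a, the p21 cell cycle inhibitor, by 1.59, Psrc1 by 0.84 and Bax by 0.55. DNA replication genes rose in 12 of 26 and fell in none, or 14 when adjusted over the list alone (median 0.19, camera adjusted p = 0.000141; adjusted p = 0.652 with an estimated correlation), led by Cdc45 (0.40) and Prim1, a primase subunit (0.27). Ribosome biogenesis genes rose in 8 of 24 and fell in 1, also when adjusted over the list alone (median 0.17, camera adjusted p = 0.00175; adjusted p = 0.676 with an estimated correlation). Nip7 and Npm1, nucleophosmin, each rose by 0.34. Of 32 ribosomal protein genes 10 rose, or 7 when adjusted over the list alone, and none fell (median 0.21, camera adjusted p = 0.000132; adjusted p = 0.698 with an estimated correlation), with Rps20 at 0.46 and Rps9 at 0.32. Glycolysis genes fell in 11 of 18 and rose in 3, or 12 and 3 when adjusted over the list alone (median -0.29, camera adjusted p = 0.0345; adjusted p = 0.676 with an estimated correlation). Slc2a1, a glucose transporter, fell by 1.55, Pfkp, a phosphofructokinase, by 1.06 and Aldoa, aldolase A, by 0.67. The glycolysis call was lost without KI_Chd7del library 1 (adjusted p = 0.0975) or 3 (0.0554) and with the filter set per library total (0.053).

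Stem cell genes did not pass as a list, with 12 of 22 higher and 5 lower, also when adjusted over the list alone (median log2 0.75, camera adjusted p = 0.0573). Fgd5, a stem cell reporter gene, rose by 1.65, whereas Ctnnal1 fell by 1.43. The stem cell list passed without KI library 1 or 3 (adjusted p = 0.0487 and 0.0476) and without KI_Chd7del library 1 (0.0259). It also passed without a filter (0.0217), in a fit of only the 2 groups (0.0457) and with a pseudocount of 16 (0.0481). Megakaryocyte genes had 8 of 18 higher and 4 lower, or 9 and 4 when adjusted over the list alone (median 0.59, camera adjusted p = 0.308). Pf4, platelet factor 4, and Gp9, a platelet receptor subunit, rose by 2.43 and 1.62, and Tubb1, a platelet tubulin (-2.61), and Clec1b, a platelet receptor (-2.39), fell. Genes linked to CBFB-MYH11 had 7 of 22 higher and 10 lower, or 8 and 11 when adjusted over the list alone (median -0.19, camera adjusted p = 0.62), with Csf2rb2 at -3.06 and Csf2rb at -1.79. Mast cell, basophil and eosinophil genes had 8 of 20 higher and 8 lower, with a median of -0.32, a mean of 0.32 and a test direction that was up (camera adjusted p = 0.654). Interferon response genes had 2 of 28 higher and 2 lower, with Ifi44 at 2.83 and Gbp2 at -1.86 (median 0.32, camera adjusted p = 0.353). Without KI_Chd7del library 1 that list passed (median 0.86, adjusted p = 0.00124). In all, 11 of 29 lists passed camera, 0 with an estimated correlation and 12 with fry. Of the lists that passed camera, fry did not call B cell, ribosome biogenesis and ribosomal protein genes (fry adjusted p = 0.0671, 0.0671 and 0.115). In simulations with 200 of 15997 genes changed between these groups, the test recovered 50.3% of 1.5-fold, 65.4% of 2-fold and 89.7% of 4-fold changes. Small changes can thus be missed. The data gave 6464 calls, for which the Benjamini-Hochberg cutoff is less strict, so these shares do not measure recovery in the data.

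Many genes moved in opposite directions in the first pair of comparisons. Of the 9429 genes called in KI against WT, 4530 (48%) were also called in KI_Chd7del against KI with the opposite sign and 356 (3.78%) with the same sign. Called or not, 81.29% had the opposite sign. Both comparisons contain the KI libraries, which by itself gives opposite signs, and 100 simulations with no change in KI_Chd7del gave 54.38% (52.77% to 55.69%). Genes that rose in KI and fell in KI_Chd7del against KI, such as Arg1, Ccl24, Ccr2 and Csf2rb2, numbered 2762, against 1164 for independent lists. Those that fell and then rose, such as S100a8, Elane, Prg2 and Kit, numbered 1768, against 761. Both tests called 198 genes higher and 158 lower, against 891 and 994 for independent lists, and Plagl1 and Flt3 were among the former. The counts for independent lists ignore the shared KI libraries. The simulations called at most 1 gene with opposite signs and at most 1 with the same sign, since they held no change in KI_Chd7del. Across genes, which are not independent replicates, the fold changes had a covariance of -0.729, against -0.0356 in the simulations, a difference of -0.693. The simulations include the sharing at the modelled spread of each gene. They drew genes independently, whereas genes moved together in the data, with an estimated correlation of 0.895 for the late neutrophil list. The simulated ranges are therefore likely too narrow. The 3 KI libraries could not be split into sets of at least 2 each, so an effect of sharing beyond that simulated stays possible. Of the 4530 genes called in opposite directions, 2149 were still called against WT in the direction of KI, 2177 were not called against WT and 204 were called the other way.

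**Figure D4:**
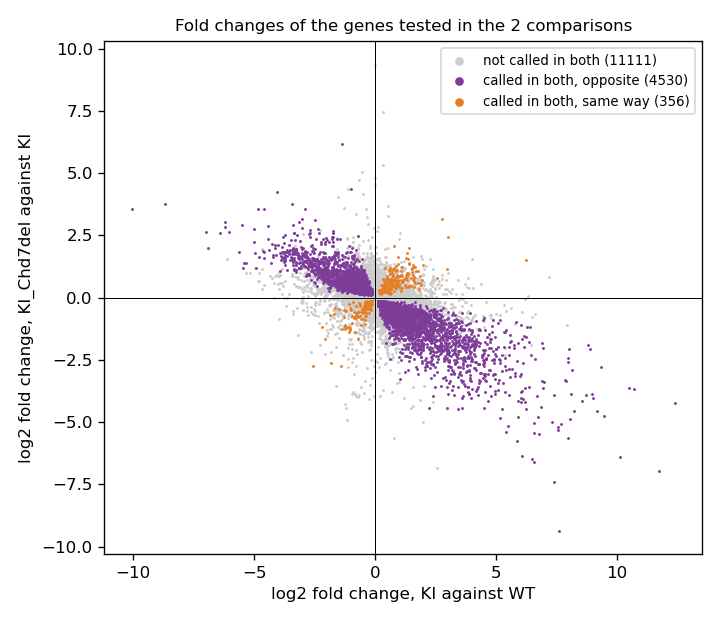
Log2 fold change of each of 15997 genes in KI against WT (horizontal axis) and in KI_Chd7del against KI (vertical axis), with 1 point per gene. Coloured points are the 4530 genes called in both comparisons with opposite signs and the 356 called in both with the same sign.

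The third comparison asked what differed from wild type in marrow with both sets of alleles. Neutrophil genes were lower in KI_Chd7del than in WT and monocyte and stem cell genes higher, while erythroid genes were lower. These list calls were lost with an estimated correlation too (adjusted p = 0.305 to 0.689). Ly6g averaged 12359 ± 2297 in WT and 1806 ± 310 in KI_Chd7del (SD, n = 3; log2 -2.77, SE 0.48, adjusted p = 0.0014). Ms4a6c rose from 1234 ± 84.6 to 4440 ± 340 (log2 1.84, SE 0.07, adjusted p = 1.89e-06) and Gata2 from 1074 ± 182 to 10518 ± 2454 (log2 3.28, SE 0.19, adjusted p = 5.02e-06). Rhd, the red cell blood group protein, fell from 3762 ± 235 to 1348 ± 18.9 (log2 -1.48, SE 0.06, adjusted p = 1.89e-06). Of 15997 genes, 7735 (48.4%) passed an adjusted p of 0.05 with limma, 3842 higher and 3893 lower, with 1588 and 967 of them changed at least 2-fold. The libraries of the groups did not overlap in 9220 genes (57.6%), against 10% by chance. Higher genes made up 49.7% of the calls. Scaled to the column total that share was 78.7%, with the median of all genes moved from 0.02 to 0.26, and without the late neutrophil genes in the total it was 65.8%, with the median at 0.14. It was 66.4% among the 1700 genes that passed a test against a 1.5-fold change.

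All 18 late neutrophil genes that passed were lower, also when adjusted over the list alone (median log2 -1.5, camera adjusted p = 2.98e-05; adjusted p = 0.689 with an estimated correlation), with Orm1, an acute phase protein, at -2.34 and Fcnb at -1.94. Of 12 early granule genes 8 fell and 1 rose, also when adjusted over the list alone (median -0.67, camera adjusted p = 0.0139; adjusted p = 0.705 with an estimated correlation), a call that quantile normalisation ended (0.102). Quantile normalisation moved the late median to -0.99, and scaling to the column total moved the early median to -0.43. Cebpe (-1.59) and Elane (-1.48) were among the lower genes. Monocyte and macrophage genes were higher in 12 of 20, or 12 with 1 lower when adjusted over the list alone (median 0.52, camera adjusted p = 0.00191; adjusted p = 0.333 with an estimated correlation). Dendritic and class II genes were higher in 13 of 16 and lower in 1, also when adjusted over the list alone (median 1.19, camera adjusted p = 9.97e-05; adjusted p = 0.268 with an estimated correlation), with Flt3 at 2.26 and Ciita at 1.73. Of 22 stem cell genes 17 rose and 1 fell, also when adjusted over the list alone (median 1.52, camera adjusted p = 7.39e-06; adjusted p = 0.305 with an estimated correlation). Tek rose by 3.27 and Slamf1 by 3.11. Of the HOX and MEIS family genes 8 of 12 rose, also when adjusted over the list alone (median 0.65, camera adjusted p = 0.0132; adjusted p = 0.295 with an estimated correlation), with Hoxa10 at 1.56 and Meis1, a stem cell homeobox gene, at 1.39. The HOX and MEIS call was lost when scaled to the column total (0.0909) and with the filter set per library total (0.0837), and the median was 1.35 without a filter and 0.42 with quantile normalisation.

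Erythroid genes fell in 15 of 24, or 17 when adjusted over the list alone, and none rose (median log2 -0.7, camera adjusted p = 3.52e-06; adjusted p = 0.333 with an estimated correlation), with Trim10 at -2.54 and Epb42 at -1.47. Of 13 heme synthesis genes 10 fell and none rose, also when adjusted over the list alone (median -0.73, camera adjusted p = 4.69e-05; adjusted p = 0.268 with an estimated correlation), among them Uros (-1.32). Mitosis genes fell in 20 of 22, also when adjusted over the list alone (median -0.4, camera adjusted p = 1.7e-07; adjusted p = 0.333 with an estimated correlation). DNA replication genes fell in 18 of 26 and rose in 2, or 20 and 2 when adjusted over the list alone (median -0.31, camera adjusted p = 7.39e-06; adjusted p = 0.333 with an estimated correlation). Rrm2 fell by 0.82 and Cdc20, a mitotic exit factor, by 0.53. Scaled to the column total, the medians of these 2 lists were -0.15 and -0.07. Chromatin remodeller genes rose in 14 of 24 and fell in 3, or 16 and 3 when adjusted over the list alone (median 0.29, camera adjusted p = 0.000464; adjusted p = 0.305 with an estimated correlation), with Chd3 at 2.15 and Kmt2a, a histone methyltransferase, at 1.19. The lower genes included Chd7 itself, a member of this list. Scaled to the column total, the chromatin remodeller median was 0.54. The same scaling moved the medians of the erythroid and heme synthesis lists to -0.45 and -0.49. B cell genes rose in 14 of 21 and fell in 6, also when adjusted over the list alone (median 1.15, camera adjusted p = 0.0368; adjusted p = 0.795 with an estimated correlation). Dntt, the terminal transferase of early lymphoid cells, rose by 2.33 and Il7r by 2.25, whereas Blk fell by 1.93. The B cell call was lost without KI_Chd7del library 3 (adjusted p = 0.0883) and when scaled to the column total with or without the late neutrophil genes (0.473 and 0.153).

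Interferon response genes rose in 7 of 28 and fell in 1, also when adjusted over the list alone (median log2 0.83, camera adjusted p = 0.0161; adjusted p = 0.809 with an estimated correlation), with Ifi44 at 2.95 and Mx1 at 2.79. This call rested on single libraries, with adjusted p = 0.167 (median 0.29) without KI_Chd7del library 3, 0.0532 without WT library 1, and 9.7e-06 (median 1.38) without KI_Chd7del library 1. It was also lost when scaled to the column total with or without the late neutrophil genes (0.296 and 0.0781). The level of the list was -0.67, 0.46 and 1.38 in the KI_Chd7del libraries and -0.7, -0.27 and -0.41 in WT. Of the genes linked to CBFB-MYH11, 13 of 22 rose and 4 fell, also when adjusted over the list alone (median log2 0.7, camera adjusted p = 0.0132; adjusted p = 0.295 with an estimated correlation), led by Myh11 (4.44) and Il1rl1 (2.92). Scaled to the column total this call was lost (0.0964), and the list was not tested without Myh11. Oxidative phosphorylation genes fell in 15 of 24, or 16 when adjusted over the list alone (median -0.22, camera adjusted p = 4.69e-05; adjusted p = 0.333 with an estimated correlation), with Ndufb7 at -0.69 and Cox5a at -0.58. Their median turned to 0.02 when scaled to the column total, which ended the call (0.0964), as did quantile normalisation (0.0749). Ribosomal protein genes rose in 8 of 32, or 0 when adjusted over the list alone (median 0.22, camera adjusted p = 0.00325; adjusted p = 0.795 with an estimated correlation), with Rps6 at 0.29. That median was 0.47 when scaled to the column total. Ribosome biogenesis genes rose in 8 of 24 and fell in 1, or 4 and 1 when adjusted over the list alone (median 0.17, camera adjusted p = 0.0417; adjusted p = 0.795 with an estimated correlation). Myc, the growth transcription factor, rose by 0.82, and the call was lost without KI_Chd7del library 2 (median 0.07, adjusted p = 0.228) or 3 (0.0612), without WT library 2 (0.0705) or 3 (0.0784), and with upper-quartile factors (0.0641). The median was 0.42 when scaled to the column total. Megakaryocyte genes rose in 9 of 18 and fell in 1, also when adjusted over the list alone (median 0.89, camera adjusted p = 0.0489; adjusted p = 0.705 with an estimated correlation), with Selp, P-selectin, at 2.69. That call was lost without KI library 1 (0.0503), KI_Chd7del library 2 (0.0694) or 3 (0.135), or WT library 2 (0.103). It was also lost when scaled to the column total with or without the late neutrophil genes (0.306 and 0.138), with quantile normalisation (0.0898), with the filter set per library total (0.0725) and with pseudocounts of 5 and 16 (0.0501 and 0.0502). Glycolysis genes fell in 9 of 18 and rose in 4, also when adjusted over the list alone (median -0.2, camera adjusted p = 0.0489; adjusted p = 0.705 with an estimated correlation), with Eno1, an enolase, at -0.64. Their median turned to 0.04 when scaled to the column total (0.0934), the call was lost with most other settings too (0.0502 to 0.328), and it held without KI_Chd7del library 2 or WT library 1 but was lost without any other (0.0503 to 0.121).

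In all, 19 of 29 lists passed camera, 0 with an estimated correlation and 16 with fry. Of the lists that passed camera, fry did not call B cell and interferon response genes (fry adjusted p = 0.0501 and 0.169). It also did not call ribosomal protein and ribosome biogenesis genes (0.118 and 0.119).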

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

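Pseudocounts, scaling to the column total, quantile normalisation and the fit without a trend were chosen after the results were seen. Called genes numbered 8095 to 9817 (KI against WT), 4657 to 6394 (KI_Chd7del against KI) and 6273 to 7884 (KI_Chd7del against WT) with any 1 library left out, and the opposite share 79.41% to 83.38%. Without KI_Chd7del library 1, which stood apart, they were 9817, 6394, 7662 and 79.41%. A test against a 1.5-fold change left 3239, 865 and 1700 genes. The opposite share was 87.57% among KI genes with at least a 2-fold change and 90.71% in the 1.5-fold test. The replicate block gave 9121, 5952 and 7411 genes and 81.95%. With it the glycolysis list (KI_Chd7del against KI, adjusted p = 0.0647) and Cenpe (0.0616) were lost, and no other listed or named call changed. Deviations of libraries with the same number correlated by -0.15 to 0.11, and those with different numbers by -0.17 to 0.21. No pairing by number was visible, but so few libraries cannot exclude it. Scaled to the column total, Cbfb in KI_Chd7del against WT turned to 0.177, and quantile normalisation turned the ribosomal protein list in KI against WT to 0.194 (adjusted p = 0.00439). The cause was not tested. With the labels of 6 libraries exchanged, there are 10 splits, and 1 of 10, the real one, reached the real count in each comparison and for opposite directions. All other splits called 0 genes with limma, and at most 622, 1261 and 675 genes had unadjusted p under 0.05, against 10123, 7976 and 8862. These splits are too few for a share under 0.05. Each of the other splits also mixes libraries of both groups, so a group difference enters their spread and lowers their counts. Their 0 calls are thus no measure of what chance alone would give.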

Other observations

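The receptors and transcription factors in this paragraph were chosen after their values were seen. They are single genes and say nothing of receptors or regulators as groups, since 48% of all genes called in KI were also called the opposite way in KI_Chd7del against KI. Csf2rb, the shared beta chain of the IL-3, IL-5 and GM-CSF receptors, rose by 2.35 on the log2 scale in KI (limma adjusted p = 1.94e-06) and changed by -1.79 in KI_Chd7del against KI (adjusted p = 6.1e-05). Its mouse paralog Csf2rb2, with which it can share reads, changed by 4.67 and -3.06. Csf1r, the macrophage growth factor receptor, changed by 2.68 and -1.13, and Il6ra, the interleukin-6 receptor, by 1.54 and -0.50. The partner chain Il3ra rose by 0.61 in KI and did not pass against KI (-0.11, adjusted p = 0.423). Flt3 went up at both steps (1.59 and 0.67). Among transcription factors, Cebpe (-3.41 and 1.82) and Cebpd (-1.84 and 0.86), of granulocyte maturation, and Myb, of progenitors (-0.61 and 0.91), fell and then rose. Klf4, of monocytes (2.57 and -0.88), and Gata1, of erythroid and mast cells (0.88 and -1.09), went the other way. Spi1, the macrophage and granulocyte regulator, fell in KI (-0.84) and did not pass in KI_Chd7del against KI (0.11, adjusted p = 0.217). Irf8, of monocytes and dendritic cells, rose at both steps (0.98 and 0.56).

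The interferon test here was written after the result was seen and its terms were revised after its outcome was known. The chromosome segment test was written before, and its control in KI against WT was added after its outcome. Ifi202b was listed at 0 in all WT and KI libraries and had 355, 1074 and 751 in KI_Chd7del. An interferon response might raise it: of the 6 libraries with Ifi202b at 0, 5 had an interferon list level above the lowest KI_Chd7del library, but that is library 1 alone (-0.67), which also had the least Ifi202b. The other KI_Chd7del libraries lay above all WT and KI libraries, at 1.38 and, barely, at 0.46 (library 2), while KI library 2 reached 0.4 with Ifi202b at 0, and these single libraries leave an interferon response open. Ifi202b is known to be silent in C57BL/6 and expressed in some other strains. A chromosome 1 segment of another strain carried by the floxed mice could thus explain it. Chd7 itself is on chromosome 4, so such a segment would not be linked to the floxed allele. Genes within 10 Mb of Ifi202b were enriched for calls of at least 2-fold in KI_Chd7del against KI (odds ratio 1.49, 95% confidence interval 1.01 to 2.15, Fisher exact p = 0.034). Windows of the same size around Chd7 and Cbfb were not enriched there (odds ratios 0.72 and 0.64, Fisher exact p = 0.572 and 0.162). The Ifi202b window was also enriched in KI against WT (1.84, Fisher exact p = 4.85e-05). Fisher's test treats neighbouring genes as independent, which they may not be, so a strain segment stays open. Ceacam3, Ighv1-29, Ighv8-11 and Ighv3-2 were also above a value of 2 only in KI_Chd7del, and Hmgb1-ps8 was near 0 only there.

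Both tests in this paragraph were written after the results were seen, and both were revised after their outcomes were known. Late neutrophil genes fell in KI, and fewer mature neutrophils carried through the c-KIT selection could give that fall. The members fell by different amounts, with an SD of their fold changes 2.19 times their median standard error, where a loss of cells that alone express them would lower all alike. Members that other cells also express would fall less, which was not measured. The standard error reflects the spread between libraries, which the members share, so this ratio is no formal test of a common fall. The early granule median was -1.56 with the late genes left out of the total, which decides nothing, since how much of these transcripts mature neutrophils carry was not measured. The loss of such cells stays open for both lists. A block of granulocyte maturation in the progenitors themselves could lower both lists, which these bulk values were not used to test.

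Both tests in this paragraph were written after the results were seen, and the smooth muscle test was revised once its outcome was known. Myh11 rose in both groups with the Cbfb+/56M allele. Smooth muscle cells in the sample might bring it. The other smooth muscle genes did not rise as a set, with a median of -0.27 in KI against WT and Acta2 at -1.25. Cnn1 (3.73), Mylk (1.38) and Synpo2 (1.15), also of smooth muscle, did rise, so this test does not exclude such cells. Reads of the fusion transcript counted at mouse Myh11 could explain its level, which differed by -0.16 between KI_Chd7del and KI, and this stays open because gene totals do not show where in Myh11 the reads lie.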
